A study of Mus musculus with 16 samples.

How the data were processed

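Liver RNA of C57BL/6 mice was sequenced after young mice (5 months) and old mice (23 months) had received, by rapid injection of a large volume into the tail vein, an enhanced episomal vector (EEV) plasmid that coded for human MANF or an empty control plasmid. Livers were collected 5 weeks later. There were 4 animals in each of the 4 groups (young control, young MANF, old control and old MANF), 1 library per animal and 16 libraries in all. Per the labels, RNA was extracted with Trizol from flash frozen tissue and libraries were made with the TruSeq Stranded mRNA LT kit. Sex was not stated in the labels. Ddx3y, a gene of the Y chromosome, was read at 4.02 to 13.6 RPKM in the 16 libraries, and Xist, which is transcribed from an inactive X chromosome, at no more than 0.0076 RPKM.

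The deposited table held RPKM values (reads per kilobase of gene length, relative to the size of the library) that the authors had computed for 24010 table entries in the 16 libraries. The submitters' processing notes name STAR 2.4.2a, HTSeq without a version and the mm10 assembly, and do not say how the steps were combined. Of the entries, 6664 had a value of 0 in every library, and 24 carried a date number in place of a gene symbol and were left unnamed. The whole numbers of reads behind the values were recovered from the spacing of the values within each library, since the smallest step between values of 1 gene corresponds to 1 read. All values above 0 (100%) came out whole within a tolerance of 0.001 reads, widened for genes with many reads to at most 0.2 reads, and the largest distance from a whole number was 0.00449 reads. In 3000 simulated genes, 100% of those with at least 50 reads were recovered exactly. The number of reads that the RPKM had been divided by was 18.31 to 26.12 M (M, megareads) per library, of which 11.85 to 16.58 M lay in the listed genes. An RPKM of 1 for a gene of 2 kb corresponded to 36.6 to 52.2 reads. Gene positions were taken from GENCODE M21 (GRCm38), in which 23562 symbols of the table matched a single gene. The major urinary protein (Mup) genes are close paralogs, and how reads that align to several of them were assigned is not stated.

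Genes with at least 0.5 RPKM in at least 4 of the 16 libraries were tested, which kept 10677 genes and left out 13333. Values were analysed as log2(RPKM + 0.5). Linear models with a mean per group were fitted to all 16 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. The 6 contrasts were old against young in control mice, old against young in MANF mice, MANF against control in young mice, MANF against control in old mice, the mean of these last contrasts over both ages, and their difference between the ages (the interaction). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 10677 genes of each contrast. A gene was called at an adjusted p below 0.05. Differences are given as log2 changes on this scale, which for genes near 0.5 RPKM or below are smaller than the ratio of the RPKM themselves. Group values are means ± SD of RPKM with n = 4. Manf itself was also compared with exact two-sided permutation tests.

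There were 38 gene lists with 659 different symbols, of which 14 were not in the table. They cover hepatocyte metabolism and secretion, stress responses, inflammation, and markers of other cell types or tissues that a piece of liver holds or could carry. The 35 lists with at least 3 tested genes were compared with all other tested genes by camera with a preset correlation of 0.01 between genes, adjusted by Benjamini-Hochberg over the lists of each contrast. Beside it stand camera with a correlation estimated for each list, and fry, which tests whether the genes of a list move on balance in one direction. Marker lists describe RNA in a bulk sample and give no cell numbers. Members of a list were counted as higher or lower when adjusted over all genes and when adjusted over the list alone.

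The lists, the contrasts, their tests and the rule for naming genes were set before the data were examined. The rule took, for each contrast, the 10 called genes with the largest rise and the 10 with the largest fall among genes with a mean of at least 1 RPKM in a compared group. With fewer than 5 calls it added the 5 genes with the smallest unadjusted p. It further took Manf and Cdnf, up to 4 members with the smallest p of each called list, and up to 4 members of the lists for endoplasmic reticulum (ER) stress, cytokines, Kupffer cells, stellate cells and lipid synthesis whether called or not. Predicted genes could be summarised by number. The rule took 261 different genes, 119 genes are named as results of a contrast, and 15 of these were chosen for at least 1 contrast after their values were seen. These are Eng, Hspa8, Rrm2, Cdkn1a, Phlda3, Cd36, Dbp, Hspa5, Per2, Cry1, Usp2, Bhlhe41, Hlf, Clock and Nfil3.

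The pipeline was tested on simulated data with the same groups. Of 100 genes changed by a log2 of 1, between 91 and 97 were called in each contrast other than the interaction, in which 69 were called. Of 10477 unchanged genes, 5 to 13 were called. In these simulations the noise was independent between genes, no library stood apart and no shift affected all genes. The rates therefore need not hold for the real libraries, in which the calls changed when 1 library was left out. The alternatives tried were pseudocounts of 0.1 and 1, no filter on low values, a minimum of 2 RPKM, scaling of each library to the median ratio, quantile normalization, robust empirical Bayes, the replicate number as a block, only the compared groups in the fit, and leaving out each library in turn. Voom on the recovered reads, leaving out 2 libraries together and the lists without each library were added later. The concordance of contrasts was measured across genes, which are not independent replicates, against simulated unchanged groups where contrasts share libraries. Recovery of reads and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No batch, date or pairing of animals is given in the labels.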

Results

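Gene expression was measured by RNA sequencing in livers of 16 mice, 4 in each of 4 groups. The groups were young control, young MANF, old control and old MANF mice, where MANF stands for a plasmid coding for human mesencephalic astrocyte-derived neurotrophic factor, a protein that resides in the ER and is also secreted, and control for an empty plasmid. The reads behind the RPKM numbered 21.74 ± 3.24 M in young control, 22.98 ± 3.11 M in young MANF, 21.58 ± 0.62 M in old control and 20.51 ± 1.58 M in old MANF libraries (mean ± SD, n = 4). At least 1 RPKM was reached by 8634 ± 203 genes in young control, 8277 ± 264 in young MANF, 8922 ± 395 in old control and 9016 ± 83.4 in old MANF libraries. Albumin took 6.84 to 11.8% of the reads in listed genes. The first principal component held 37.4% of the variance of the tested genes and the second 13.7%. Young MANF replicate 3 and old control replicate 4 lay furthest from the other 3 libraries of their groups, with root mean square log2 deviations of 0.472 and 0.553, against 0.241 to 0.369 in the other 14 libraries.

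**Figure D1:**
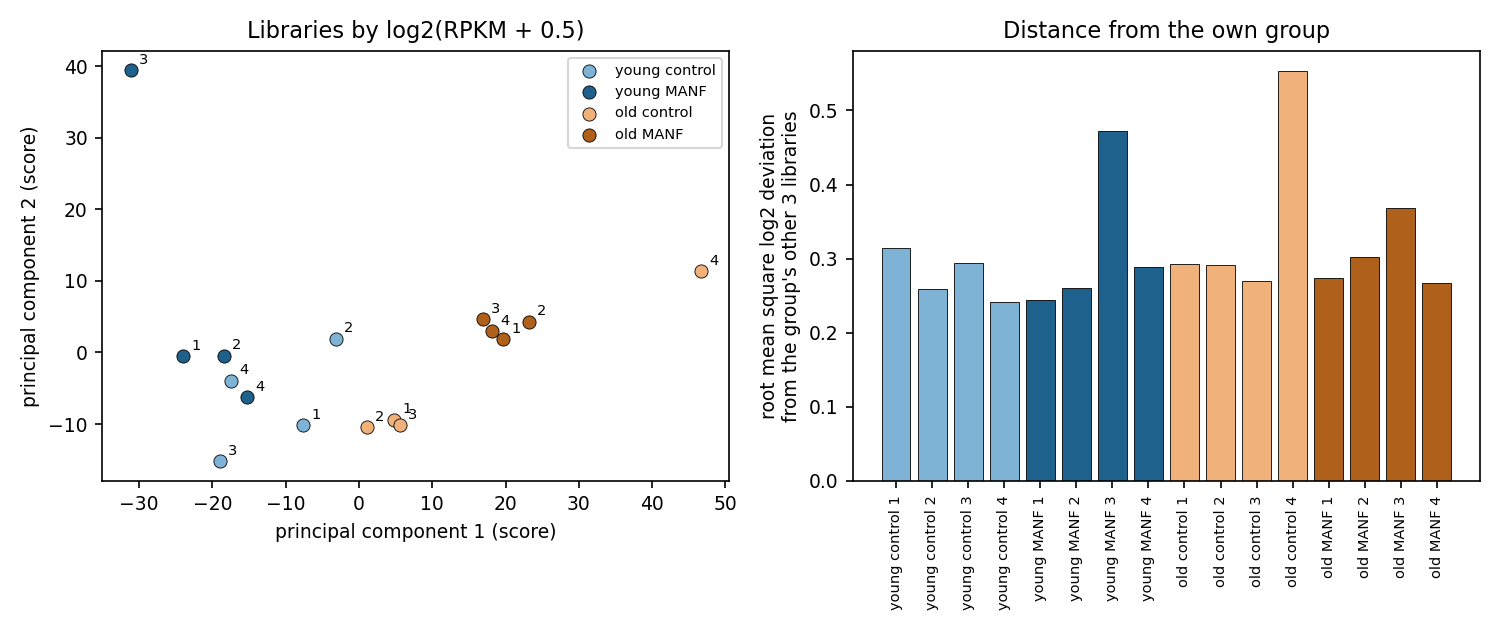
The left panel places the 16 libraries on the first and second principal components (37.4% and 13.7% of the variance of the tested genes), and the right panel shows each library's root mean square log2 deviation from the mean of the other 3 libraries of its group. Old control replicate 4 (0.553) and young MANF replicate 3 (0.472) have the largest deviations.

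The first question was whether the plasmid could be seen in the RNA. The mouse Manf gene (chromosome 9, 106838312 to 106891979, minus strand, GRCm38) was read at 10.15 ± 2.86 RPKM in young control and 11.42 ± 2.70 RPKM in young MANF livers, a log2 difference of 0.16 (exact permutation p = 0.486). The Manf difference in young mice was 0.338 without young control replicate 1 (14.44 RPKM, other young controls 8.57 to 8.95), 0.343 without young MANF replicate 2, 0.067 without young MANF replicate 1, and 0.102 and 0.098 without young control replicates 2 and 4, with adjusted p of at least 0.39. In old livers it was read at 6.77 ± 1.08 RPKM in control and 14.46 ± 3.61 RPKM in MANF mice, a log2 difference of 1.02 or 2.03-fold (exact permutation p = 0.0286, the smallest that 4 against 4 animals can give). In limma the adjusted p over all genes was 0.0746 in old mice, and 0.03 without old control replicate 4. Between the control groups Manf was 0.693-fold in old against young mice (exact permutation p = 0.0286, limma adjusted p = 0.243). The difference between the ages in the effect of the plasmid had a log2 of 0.86 (unadjusted p = 0.011, adjusted p = 0.594). Reads of the human sequence could be counted only where they aligned to the mouse gene, so these values are no measure of the expression of the plasmid. A change of the mouse gene itself and reads from the plasmid could not be told apart. Cdnf, the paralog of Manf, was read at 0.13 to 0.16 RPKM in the 4 groups, below the minimum for testing.

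Age was compared in control mice to give the baseline of liver ageing in this design. Several genes of the major urinary proteins, which hepatocytes secrete and which carry pheromones in urine, were lower in old livers. Mup17 (chromosome 4, 61591929 to 61595871, minus strand) fell from 352 ± 84.7 to 12.1 ± 9.80 RPKM (log2 -5.28, adjusted p = 0.00147), and Mup15 from 1021 ± 296 to 39.5 ± 34.3 RPKM (log2 -5.27, adjusted p = 0.00214). Mup18, Mup9, Mup16 and Mup8 fell as well, with log2 changes of -3.65, -2.49, -2.48 and -1.90. The glucuronosyltransferase Ugt2b37 (chromosome 5, 87240493 to 87254804, minus strand) fell from 5.92 ± 2.14 to 0.418 ± 0.162 RPKM (log2 -2.77, adjusted p = 2.35e-05), and its relative Ugt2b38 from 22.3 ± 5.79 to 3.69 ± 1.98 RPKM (log2 -2.56, adjusted p = 0.00147). Moxd1 fell from 11.99 ± 7.28 to 0.03 ± 0.03 RPKM, and Cdh1, which codes for E-cadherin, from 6.70 ± 1.90 to 1.62 ± 0.319 RPKM. The male-biased list joins genes higher in male than in female liver with growth hormone axis genes such as Igf1, Igfals, Ghr and Socs2. Of its 21 genes 1 fell (Ugt2b38), 9 fell when adjusted over the list alone, and 2 had a log2 change above 0. The median log2 change of the list was -0.68 (camera adjusted p = 6.13e-13, and adjusted p = 0.118 with an estimated correlation). Cyp7b1, a member that did not pass, had a log2 change of -0.95 (adjusted p = 0.0759). Of the genes named here as falling, Mup8, Mup16 and Cdh1 lost their calls in runs that left out 1 library, with adjusted p up to 0.098, 0.16 and 0.069. The libraries concerned were young control replicates 1 to 4 and old control replicates 1, 3 and 4. Moxd1 was not called by voom on the recovered reads (adjusted p = 0.15).

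The genes that rose most in old control livers were Rgs16, a regulator of G protein signalling, and Serpinb1a, an inhibitor of neutrophil proteases. Serpinb1a (chromosome 13, 32842092 to 32851185, minus strand) rose from 0.634 ± 0.181 to 7.23 ± 1.73 RPKM (log2 2.75, adjusted p = 0.00214). Raet1d, a ligand of an activating receptor of natural killer cells, rose from 3.71 ± 0.634 to 19.2 ± 8.49 RPKM (log2 2.15, adjusted p = 0.00214), and Cdh19 from 0.029 ± 0.027 to 1.19 ± 0.633 RPKM (log2 1.61, adjusted p = 0.000842). The fatty acid transporter Cd36 rose from 6.00 ± 2.38 to 17.2 ± 2.61 RPKM (log2 1.51, adjusted p = 0.00195). Rgs16 rose 8.20-fold, from 10.4 ± 11.6 to 62.3 ± 13.4 RPKM. Its young control mean included 27.5 RPKM in replicate 3, against 2.54 to 6.48 RPKM in the other young controls. Slc22a26, Ptprcap, Gimap4 and the noncoding gene Hectd2os rose by log2 1.45, 1.396, 1.34 and 1.34. The calls of Rgs16, Slc22a26, Ptprcap, Gimap4 and Hectd2os were lost in runs without 1 of young control replicates 1 to 4 or old control replicates 1 to 4, with adjusted p up to 0.11.

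RNA of lymphocyte and endothelial markers was higher in old than in young control livers. Of 12 tested markers of T and NK cells, 4 rose, 11 rose when adjusted over the list alone, and 12 of 12 had a log2 change above 0 (median 0.95, camera adjusted p = 3.47e-09, and adjusted p = 0.393 with an estimated correlation). They included Cd8a and Cd8b1, the chains of the CD8 coreceptor, with log2 changes of 1.05 and 1.33, and Nkg7, a granule protein of cytotoxic cells, with 1.68. Of 13 sinusoidal endothelium markers, 5 rose, 12 rose when adjusted over the list alone and 13 were above 0 (median 0.92, camera adjusted p = 7.56e-12, and adjusted p = 0.378 with an estimated correlation). Oit3 rose from 2.65 ± 0.346 to 6.28 ± 0.817 RPKM (log2 1.11, adjusted p = 0.00938), and Pecam1, Bmp2, Kdr and Eng by log2 1.02, 0.99, 0.99 and 0.85. Oit3 kept its call without any 1 of the 8 libraries. Each of the other 7 genes named here lost its call in at least 4 of these runs, every 1 of the 8 libraries ended at least 1 call, and the highest adjusted p was 0.14.

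Inflammatory gene groups were also higher in old control livers. All 30 interferon response genes had a log2 change above 0 (median 0.76, camera adjusted p = 3.47e-09, and adjusted p = 0.516 with an estimated correlation). Of these 2 rose and 13 rose when adjusted over the list alone. Ifi27 rose from 43.1 ± 7.30 to 103 ± 27.8 RPKM (log2 1.21, adjusted p = 0.011), and Rtp4 by log2 1.246, a call lost without young control replicate 1, 3 or 4 or old control replicate 1 (adjusted p up to 0.095). Of 16 Kupffer cell markers 0 rose in limma over all genes, 6 rose when adjusted over the list alone and 16 were above 0 (median 1.02, camera adjusted p = 4.88e-05, and adjusted p = 0.516 with an estimated correlation). Among them were the complement gene C1qa (15.7 ± 9.05 and 55.5 ± 58.0 RPKM, adjusted p = 0.157) and Adgre1, the gene of the F4/80 antigen (2.01 ± 0.837 and 9.10 ± 10.8 RPKM, adjusted p = 0.184). The lists of cytokines (camera adjusted p = 0.000313, 0.521 with an estimated correlation), antigen presentation by MHC class II (0.000489 and 0.516), B and plasma cells (0.00201 and 0.516) and monocyte-derived macrophages (0.00201 and 0.521) had medians of 0.76, 1.42, 0.82 and 0.88, with 0 members called over all genes and 5, 1, 4 and 3 higher when adjusted over the list alone. Markers of classical macrophage activation had an adjusted p of 0.0131 (0.516 with an estimated correlation), which became 0.101 without old control replicate 4, and markers of alternative activation 0.0228 (0.516), which became 0.101 without young control replicate 1. Mrc1, the mannose receptor and a member of the latter, rose by log2 1.22, a call lost without young control replicate 1 or 4 or old control replicate 1 (adjusted p up to 0.073). Old control replicate 4 lay above the other 3 old controls by a median log2 of 3.55 for MHC class II, 2.23 for monocyte-derived macrophages, 1.81 for cytokines, 1.68 for interferon response, 1.53 for Kupffer cells, 0.97 for T and NK cells and 0.20 for endothelium. Without it the camera adjusted p was 6.34e-05 for interferon response, 0.0011 for Kupffer cells, 0.0342 for cytokines, 0.00397 for MHC class II and 0.027 for monocyte-derived macrophages.

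Among metabolic groups, genes of lipid synthesis under SREBP-1 were higher in old control livers. Of 19, 3 rose and 9 rose when adjusted over the list alone, and 15 were above 0 (median 0.38, camera adjusted p = 0.000194, and adjusted p = 0.516 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, rose from 24.0 ± 3.73 to 55.0 ± 5.92 RPKM (log2 1.19, adjusted p = 0.00512). Acaca, the acetyl-CoA carboxylase, rose by log2 0.83 and Tkfc by 0.80. Of 17 genes of gluconeogenesis and glycolysis 1 rose, and 3 rose when adjusted over the list alone (camera adjusted p = 0.0066, 0.516 with an estimated correlation). That list lost its call without young control replicate 1 or old control replicate 1, with adjusted p up to 0.0795. Acaca and Tkfc lost theirs under median scaling and in 7 of the 8 runs that left out 1 library (young control replicates 1 to 4 and old control replicates 1 and 3 for each, old control replicate 4 for Acaca, and old control replicate 2 for Tkfc; adjusted p up to 0.13). Lists with 0 members called by limma over all genes or over the list alone and a small negative median were ER stress (median -0.02, camera adjusted p = 0.0214, 0.545 with an estimated correlation, and 0.0549 without old control replicate 2), nuclear genes of oxidative phosphorylation (-0.03, 0.0228, 0.678 with an estimated correlation, and up to 0.447 without young control replicate 2 or 3 or old control replicate 4) and cholesterol synthesis (-0.11, 0.0421, 0.781 with an estimated correlation, and up to 0.97 without young control replicate 2 or 4 or old control replicate 2 or 3). Under median scaling the adjusted p of cholesterol synthesis was 0.11.

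In limma, 133 of 10677 genes differed between old and young control livers after Benjamini-Hochberg adjustment, 96 higher and 37 lower in old mice. Median scaling gave 74 higher and 58 lower, quantile normalization 67 and 82, and voom 47 and 42. Leaving out young control replicate 1, 2, 3 or 4 left 47, 77, 74 or 37 calls, and leaving out old control replicate 1 or 3 left 44 or 50. Without both old control replicate 4 and young MANF replicate 3, a run added later, 229 genes were called. Without old control replicate 4 alone, 8 more lists were called, among them fatty acid oxidation (higher, adjusted p = 0.0011), lipid droplets (higher, 0.01), acute phase (lower, 0.00899) and stellate cells (lower, 0.0168).

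The same comparison of old with young mice was made under the MANF plasmid. Several major urinary protein genes were again lower in old livers, and so were Cyp8b1 and Cyp7b1, 2 enzymes of bile acid synthesis, and other male-biased genes. Mup15 fell from 658 ± 268 to 12.7 ± 12.3 RPKM (log2 -5.92, adjusted p = 0.000542) and Mup17 from 262 ± 135 to 4.98 ± 4.73 RPKM (log2 -5.74, adjusted p = 0.000388). Mup7, Mup11, Mup1, Mup18 and Mup16 fell by 4.80, 4.48, 3.61, 3.45 and 3.22 on the log2 scale. Mup11 was read at 72.8 RPKM in old MANF replicate 3 and at 3.14 to 12.6 RPKM in the other old MANF libraries. Cyp8b1 (chromosome 9, 121914356 to 121916305, minus strand), the sterol 12-alpha-hydroxylase that sets the share of cholic acid, fell from 169 ± 29.4 to 36.7 ± 12.7 RPKM (log2 -2.25, adjusted p = 0.000729), and Cyp7b1, the oxysterol 7-alpha-hydroxylase, from 129 ± 9.72 to 48.4 ± 22.3 RPKM (log2 -1.52, adjusted p = 0.00478). Of the 21 genes of the male-biased list, 13 fell, 16 fell when adjusted over the list alone and 1 was above 0 (median -1.16, camera adjusted p = 2.42e-32, and adjusted p = 0.00308 with an estimated correlation). They included Cyp2d9 (835 ± 186 to 331 ± 51.4 RPKM), Cyp4a12b (34.5 ± 5.96 to 13.2 ± 2.42 RPKM) and Ugt2b38 (11.9 ± 1.98 to 1.21 ± 0.655 RPKM). Hsd3b5, also in the list, fell by 3.28 and Moxd1, outside it, by 2.96 on the log2 scale. The calls of Hsd3b5 and Moxd1 were lost without young MANF replicate 1, 2 or 3 or any 1 of the 4 old MANF replicates, with adjusted p up to 0.083, whereas the other genes named here kept theirs in every such run. Among all genes named for age in MANF mice, 23 kept their calls in every such run, and 21 of them also in every other setting.

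Genes of the interferon response and of stellate cells were among those that rose with age in MANF mice. All 30 interferon response genes were above 0 (median 1.19, camera adjusted p = 4.91e-10, and adjusted p = 0.612 with an estimated correlation), 15 rose, and 27 rose when adjusted over the list alone. Ifi27 rose from 40.8 ± 6.32 to 152 ± 35.5 RPKM (log2 1.87, adjusted p = 0.000287). The 2'-5'-oligoadenylate synthetase Oas1a rose by log2 2.23 (adjusted p = 0.00883) and the ISG15 protease Usp18 by log2 1.89 (adjusted p = 0.00663). Ifi27l2b (chromosome 12, 103450898 to 103457223, minus strand) rose from 2.94 ± 0.496 to 34.8 ± 16.1 RPKM (log2 3.26, adjusted p = 0.00116). Stellate cell and fibrosis genes were all above 0 (20 of 20, median 0.87, camera adjusted p = 2.01e-05, and adjusted p = 0.612 with an estimated correlation), with 8 higher over all genes and 15 when adjusted over the list alone. The matrix proteoglycan gene Dcn rose from 46.5 ± 5.40 to 93.7 ± 9.10 RPKM (log2 1.005, adjusted p = 0.00288), and Lrat, which makes the retinyl esters that stellate cells store, by log2 0.98. The deadenylase-like gene Noct rose from 3.77 ± 2.28 to 30.9 ± 17.9 RPKM (log2 2.86, adjusted p = 0.00959). Median scaling left 7 interferon response and 2 stellate cell genes called, with list medians of 1.01 and 0.69. Lrat lost its call without young MANF replicate 2 or 3 or old MANF replicate 1, 2 or 3 (adjusted p up to 0.06), and the other genes named here kept theirs.

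Of the immune lists, some were called for age in MANF mice and others were not. Of 12 T and NK cell markers 3 rose (Cd8a, Nkg7 and Klrd1, by log2 0.97, 1.56 and 0.87), 11 rose when adjusted over the list alone and 12 were above 0 (camera adjusted p = 0.00242, and adjusted p = 0.661 with an estimated correlation). Of 19 cytokine genes 6 rose, among them the chemokines Ccl5, Ccl2 and Cxcl1 by log2 2.56, 1.87 and 1.36, and 12 rose when adjusted over the list alone (median 1.02, camera adjusted p = 0.002, and adjusted p = 0.661 with an estimated correlation). Of 11 monocyte-derived macrophage markers 3 rose, including the lipid receptor Trem2 by log2 0.90, and 11 rose when adjusted over the list alone (camera adjusted p = 0.000565, and adjusted p = 0.661 with an estimated correlation). Of 9 genes of MHC class II presentation 1 rose, cathepsin S (Ctss) by log2 1.99, and 6 rose when adjusted over the list alone (camera adjusted p = 0.0263, and adjusted p = 0.668 with an estimated correlation). That list was not called without young MANF replicate 1, 2 or 4 or old MANF replicate 1 (adjusted p up to 0.0864). Kupffer cells (camera adjusted p = 0.139, 0.828 with an estimated correlation), B and plasma cells (0.0643 and 0.661), classical macrophage activation (0.147 and 0.715), alternative activation (0.713 and 0.852) and neutrophils (0.149 and 0.661) were not called, though under median scaling all but alternative activation (0.352) were, at 0.00245, 0.00482, 0.0194 and 0.0258. Without young MANF replicate 3, Kupffer cells (0.0208), B and plasma cells (0.0354), acute phase genes (0.0354) and sinusoidal endothelium (0.0354) were called as higher. Lcn2, an iron-sequestering acute phase protein, had the largest rise (log2 3.37), and Ly6a, Jchain of secreted immunoglobulins and Cyp26a1, which degrades retinoic acid, rose by 2.44, 2.41 and 2.17. Cd8a kept its call in every run that left out 1 library. The other genes named here lost theirs in at least 3 of the 8 runs, each of the 8 libraries ended at least 1 call, and the highest adjusted p was 0.092. Lcn2, Jchain, Cyp26a1, Klrd1 and Trem2 also lost theirs under median scaling (adjusted p 0.065, 0.061, 0.077, 0.08 and 0.062).

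Several metabolic lists were lower relative to the other genes in old MANF mice, and few of their members were called. Nuclear genes of oxidative phosphorylation had a median log2 of -0.12 with 0 of 25 called by limma over all genes or over the list alone (camera adjusted p = 2.96e-12, 0.211 with an estimated correlation), and under median scaling a median of -0.295 with 2 lower. Bile acid synthesis and transport had 2 of 16 genes lower, Cyp8b1 and Cyp7b1, and 1 higher, the exporter Abcc4 by log2 0.56, with the same counts when adjusted over the list alone (camera adjusted p = 6.95e-08, 0.0728 with an estimated correlation). Abcc4 passed at an adjusted p of 0.0499 and lost the call in each of the 8 runs that left out 1 library (adjusted p up to 0.11). Xenobiotic metabolism had 3 of 22 genes lower (Ugt2b1 by log2 -1.003, Cyp2d9 by -1.32 and Cyp1a2 by -1.10) and 1 higher, Cyp2a4, which rose from 0.173 ± 0.044 to 5.83 ± 3.48 RPKM (log2 3.05, adjusted p = 0.00349) and is more abundant in female than in male mouse liver. When adjusted over the list alone 4 were higher and 3 lower. This list had a median of 0.11 and a mean of 0.25, while camera placed it below the other genes (adjusted p = 0.0213, 0.211 with an estimated correlation), a call lost without young MANF replicate 3 or old MANF replicate 3 (adjusted p up to 0.091) and under median scaling (0.402). Cyp1a2 lost its call without young MANF replicate 1, 3 or 4 or old MANF replicate 2 or 4 (adjusted p up to 0.11). Fatty acid oxidation had a median of -0.02 and a mean of 0.12, with 0 genes called by limma and a lower rank in camera (adjusted p = 0.00129, 0.661 with an estimated correlation, and 0.0606 under median scaling). Adipose markers (5 tested, 0 called) had an adjusted p of 0.0331 (0.211 with an estimated correlation), and up to 0.0729 without young MANF replicate 3, old MANF replicate 2 or old MANF replicate 3 and 0.201 under median scaling. Acly rose by log2 0.99 (adjusted p = 0.00944), and Manf had a log2 difference of 0.33 (adjusted p = 0.275).

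In limma, 702 genes differed with age in MANF mice, 625 higher and 77 lower in old livers. The median log2 change of all genes was 0.184 here, and 0.008 after each library had been scaled to its median ratio, a shift of 0.176. Of the reads that the RPKM had been divided by, 63.92 ± 0.94% lay in listed genes in young MANF and 68.7 ± 0.45% in old MANF libraries. How far this share accounts for the shift was not tested. Median scaling gave 319 calls, 119 higher and 200 lower, of which 195 were among the 702. Quantile normalization gave 76 higher and 171 lower, and voom 172 and 88. With young MANF replicate 1, 2, 3 or 4 left out there were 217, 284, 238 or 1125 calls, and with old MANF replicate 1, 2, 3 or 4 left out 261, 216, 350 or 217. Without both old control replicate 4 and young MANF replicate 3 there were 1406. Old control replicate 4 is in neither group compared here, so its removal acts only through the spread estimated over all libraries.

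The age changes of control and MANF mice, which share no libraries, were correlated across the 10677 genes (Pearson r = 0.64, Spearman rho = 0.464). Both comparisons called 70 genes, 47 higher and 23 lower in old mice, where 5.62 and 0.267 would be shared if the calls were unrelated. Of the 133 genes called in control mice, 3 had the opposite sign in MANF mice. The effect of MANF in old mice was compared with the age change in control mice to ask whether the plasmid moved age-dependent genes back toward young levels. The correlation across genes was negative (Pearson r = -0.191, Spearman rho = -0.287), but the old controls enter both contrasts with opposite sign, and simulated groups without any change gave r = -0.498. The covariance of the log2 changes was -0.0145, and -0.0169 in the simulations. Of the 133 genes 89 had opposite signs (66.9%). In the simulations 66.6% of all genes did. That share was not taken among genes selected for an age change, so it is no reference for the 133. With the old controls split so that no library was shared, r averaged 0.049 over 6 splits (-0.202 to 0.273). This mean joins opposite results that follow 1 mouse. With old control replicate 4 used for the age change r was 0.197 to 0.273, and with it used for the effect of MANF -0.202 to -0.062.

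**Figure D2:**
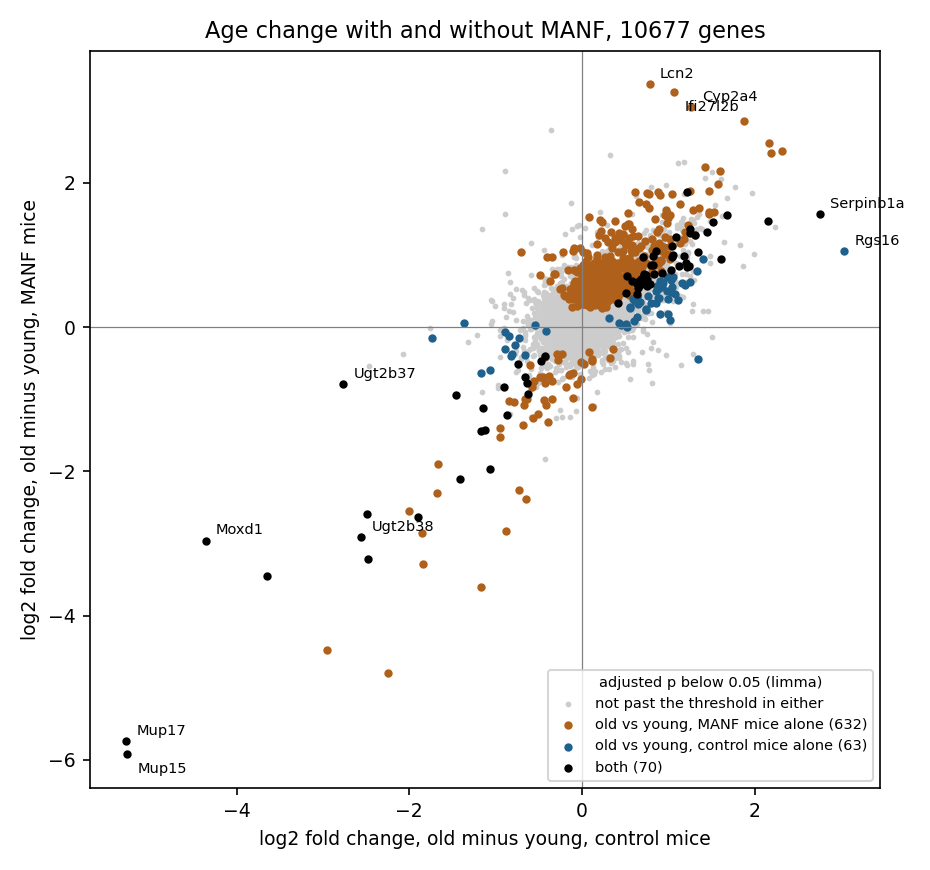
Each point is a gene, with its log2 change from young to old in control mice on the horizontal axis and in MANF mice on the vertical axis, coloured by the comparison that called it. The 70 genes called in both lie in the lower left and upper right. Calls in control mice alone numbered 63, and calls in MANF mice alone 632. These counts do not test whether age changes differ between the plasmids. The interaction, which does, called 0 genes in limma (smallest adjusted p 0.16). Median scaling lowered the calls for age in MANF mice from 702 to 319.

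MANF was next compared with control plasmid in young mice. Nr1d1 (chromosome 11, 98767932 to 98775333, minus strand), the clock repressor REV-ERB alpha, rose from 6.46 ± 1.10 to 18.8 ± 4.35 RPKM (log2 1.46, 2.75-fold, adjusted p = 0.00127), and each of the 4 MANF mice lay above all 4 controls. Ugt2b37 fell from 5.92 ± 2.14 to 1.10 ± 0.288 RPKM (log2 -1.96, adjusted p = 0.00127). These were the 2 genes that limma called, and both kept their calls without any 1 of the 8 libraries. In limma 1590 genes had an unadjusted p under 0.05. The genes with the next smallest p, Zfp36l2 (log2 -0.74), the predicted gene Gm15408 (1.11) and Tmem41a (-0.74), each had an adjusted p of 0.0841 and did not pass. Tmem41a passed without young MANF replicate 3 (adjusted p = 0.034). Dbp, a clock output transcription factor, was read at 16.7 ± 3.97 and 31.2 ± 6.59 RPKM (log2 0.89, adjusted p = 0.128), with all 4 MANF mice above all 4 controls.

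Acute phase genes were lower in young MANF than in young control livers. Of 20 tested, 0 had a log2 change above 0, 0 passed in limma over all genes and 6 fell when adjusted over the list alone (median -0.63, camera adjusted p = 2.23e-05, and adjusted p = 0.66 with an estimated correlation). Saa2, a serum amyloid A gene, was read at 72.2 ± 46.2 RPKM in control and 4.21 ± 1.56 RPKM in MANF livers (adjusted p = 0.15), and Serpina3m at 98.6 ± 9.20 and 57.8 ± 14.6 RPKM (adjusted p = 0.15). Lists that lay above the other genes had 0 members called by limma over all genes. They were oxidative phosphorylation (median 0.12, camera adjusted p = 8.78e-08, 0.41 with an estimated correlation), sinusoidal endothelium (0.31, 8.6e-07, and 0.41 with an estimated correlation), lipid synthesis (0.32, 1.26e-06, and 0.41 with an estimated correlation), cytosolic ribosome (0.10, 4.42e-05, and 0.906 with an estimated correlation), xenobiotic metabolism (0.17, 0.00289, and 0.244 with an estimated correlation) and hepatocyte secretory proteins (0.09, 0.00289, and 0.34 with an estimated correlation). When adjusted over the list alone 1 endothelium gene was higher and 0 genes of the other 5 lists. Oit3 was read at 2.65 ± 0.346 and 4.55 ± 1.16 RPKM (adjusted p = 0.216) and Fasn, the fatty acid synthase, at 13.3 ± 4.62 and 24.3 ± 3.66 RPKM (adjusted p = 0.243). The ribosome list rested on young MANF replicate 3 (adjusted p = 0.115 without it), in which it lay at a median log2 of 0.27 above the other 3 young MANF libraries. Cholesterol synthesis (0.00951) and gluconeogenesis and glycolysis (0.047) were called as higher without that library, and not with it.

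The 4 remaining lists called in young mice depended on single libraries and on the scaling. Bile acid synthesis and transport (camera adjusted p = 0.0163, 0.508 with an estimated correlation) was lost without young control replicate 1 or 2 or young MANF replicate 4 (adjusted p up to 0.124), and erythroid markers (0.0167, and 0.66 with an estimated correlation) without young control replicate 1 or 3 or young MANF replicate 2 or 3 (up to 0.124). The male-biased list (0.0231, and 0.777 with an estimated correlation) was lost without young control replicate 1 or 2 (up to 0.285), and adipose markers (0.0482, and 0.34 with an estimated correlation) without young control replicate 2 or 3 or young MANF replicate 2 or 3 (up to 0.125). Under median scaling the adjusted p of these lists were 0.0717, 0.117, 0.144 and 0.136. When adjusted over the list alone 1 bile acid and 1 erythroid gene were higher.

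In old mice the same comparison called 11 genes, 8 higher and 3 lower with MANF. Dio1 (chromosome 4, 107291465 to 107307169, minus strand), the deiodinase that converts thyroxine to active thyroid hormone, fell from 35.5 ± 5.19 to 13.4 ± 2.91 RPKM (log2 -1.39, adjusted p = 0.00102). Nr1d1 rose from 7.44 ± 0.281 to 20.004 ± 4.77 RPKM (log2 1.34, adjusted p = 0.00345), with all 4 MANF mice above all 4 controls, and Dbp was read at 16.8 ± 3.31 and 29.2 ± 5.50 RPKM (adjusted p = 0.137, and 0.045 without old control replicate 4). Cyp2c55, the neurotrophin receptor gene Ngfr, Mageh1, the tricellular junction gene Marveld2, Rhou, Dixdc1 and the kynurenine aminotransferase gene Kyat1 rose by log2 1.4003, 0.96, 0.82, 0.82, 0.76, 0.75 and 0.57. The growth factor gene Fgf1 fell by log2 -0.93 and the thioesterase gene Acot11 by log2 -0.92. Dio1 and Nr1d1 kept their calls in every run that left out 1 library, while each of the other 9 genes lost its call in 5 runs, those without old control replicate 2, old control replicate 3, old MANF replicate 2, old MANF replicate 3 and old MANF replicate 4, and all of them but Acot11 also without old control replicate 1 (adjusted p up to 0.18). The count was 4, 2, 2 or 146 without old control replicate 1, 2, 3 or 4, and 23, 2, 3 or 3 without old MANF replicate 1, 2, 3 or 4. At an unadjusted p under 0.05 limma had 1036 genes.

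ER stress genes were higher with MANF in old livers. Of 25, 22 had a log2 change above 0, 0 passed in limma over all genes and 9 rose when adjusted over the list alone (median 0.32, camera adjusted p = 4.15e-07, and adjusted p = 0.404 with an estimated correlation). The ER chaperones Hspa5 (68.3 ± 2.46 and 109 ± 24.1 RPKM, adjusted p = 0.202), Dnajb11 (12.7 ± 1.08 and 17.97 ± 3.34 RPKM, adjusted p = 0.151), Pdia4 (30.7 ± 5.56 and 48.7 ± 9.38 RPKM, adjusted p = 0.157) and Calr (118 ± 19.1 and 163 ± 25.0 RPKM, adjusted p = 0.182) did not pass over all genes, nor did the stress-induced pseudokinase Trib3 (1.49 ± 0.446 and 3.52 ± 1.85 RPKM, adjusted p = 0.17). Stellate cell and fibrosis genes had 20 of 20 above 0, 0 called by limma over all genes and 5 higher when adjusted over the list alone (median 0.50, camera adjusted p = 1.16e-06, and adjusted p = 0.772 with an estimated correlation). Lrat was read at 1.97 ± 0.699 and 3.83 ± 0.807 RPKM (adjusted p = 0.146), Pdgfrb at 0.975 ± 0.502 and 1.78 ± 0.144 RPKM (adjusted p = 0.202) and Dcn at 66.1 ± 8.21 and 93.7 ± 9.10 RPKM (adjusted p = 0.202). Calr, Lrat and Pdgfrb passed without old control replicate 4, at adjusted p of 0.046, 0.042 and 0.028. Without old control replicate 4, in which the stellate cell genes lay at a median log2 of 0.99 above the other 3 old controls and the ER stress genes at 0.22, the adjusted p of these lists were 1.47e-11 and 3.01e-05.

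Further lists had 0 members called by limma over all genes in old mice. The male-biased list had a median of -0.29 and 4 genes lower when adjusted over the list alone (camera adjusted p = 7.58e-06, 0.42 with an estimated correlation). Cyp2d9 was read at 625 ± 194 and 331 ± 51.4 RPKM (adjusted p = 0.106). Bile acid synthesis and transport had 1 gene higher and 1 lower when adjusted over the list alone (camera adjusted p = 8.64e-05, 0.404 with an estimated correlation), with Cyp8b1 at 85.7 ± 37.8 and 36.7 ± 12.7 RPKM (adjusted p = 0.129) and the bile salt export pump gene Abcb11 at 47.8 ± 4.42 and 69.8 ± 10.6 RPKM (adjusted p = 0.137). Cholesterol synthesis had 19 of 20 genes above 0 and a median of 0.38 (camera adjusted p = 0.00114, 0.848 with an estimated correlation), with 0 higher over the list alone. Sc5d was read at 36.7 ± 4.43 and 58.3 ± 9.44 RPKM (adjusted p = 0.239). Fatty acid oxidation (median -0.15, camera adjusted p = 6.87e-05, 0.772 with an estimated correlation) lost its call without old control replicate 1 (0.0708). T and NK cell markers (median -0.42, camera adjusted p = 0.000854, 0.772 with an estimated correlation) lost theirs without old control replicate 4 (0.0808), and Kupffer cell markers (median -0.13, camera adjusted p = 0.0102, 0.848 with an estimated correlation) without old control replicate 4 or old MANF replicate 2 (up to 0.672) and under median scaling (0.0868). Cd8b1 was read at 1.21 ± 0.919 and 0.433 ± 0.220 RPKM (adjusted p = 0.311) and Cd163, a scavenger receptor of macrophages, at 1.99 ± 0.679 and 0.452 ± 0.189 RPKM (adjusted p = 0.143). The ribosome list (median 0.11, camera adjusted p = 0.0102, 0.93 with an estimated correlation) was lost without old control replicate 1 or 2 (up to 0.194). Without old control replicate 4, 7 lists were called that were not called with it. Interferon response (adjusted p = 6.32e-10, against 0.132 with all libraries and 0.0304 under median scaling), monocyte-derived macrophages (3.09e-05 and 0.412), MHC class II (3.3e-05 and 0.864), cytokines (0.0349 and 0.402), classical macrophage activation (0.0483 and 0.687) and cholangiocytes (0.0483 and 0.132) were then higher with MANF, and gluconeogenesis and glycolysis (0.00178 and 0.0593) lower.

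**Figure D3:**
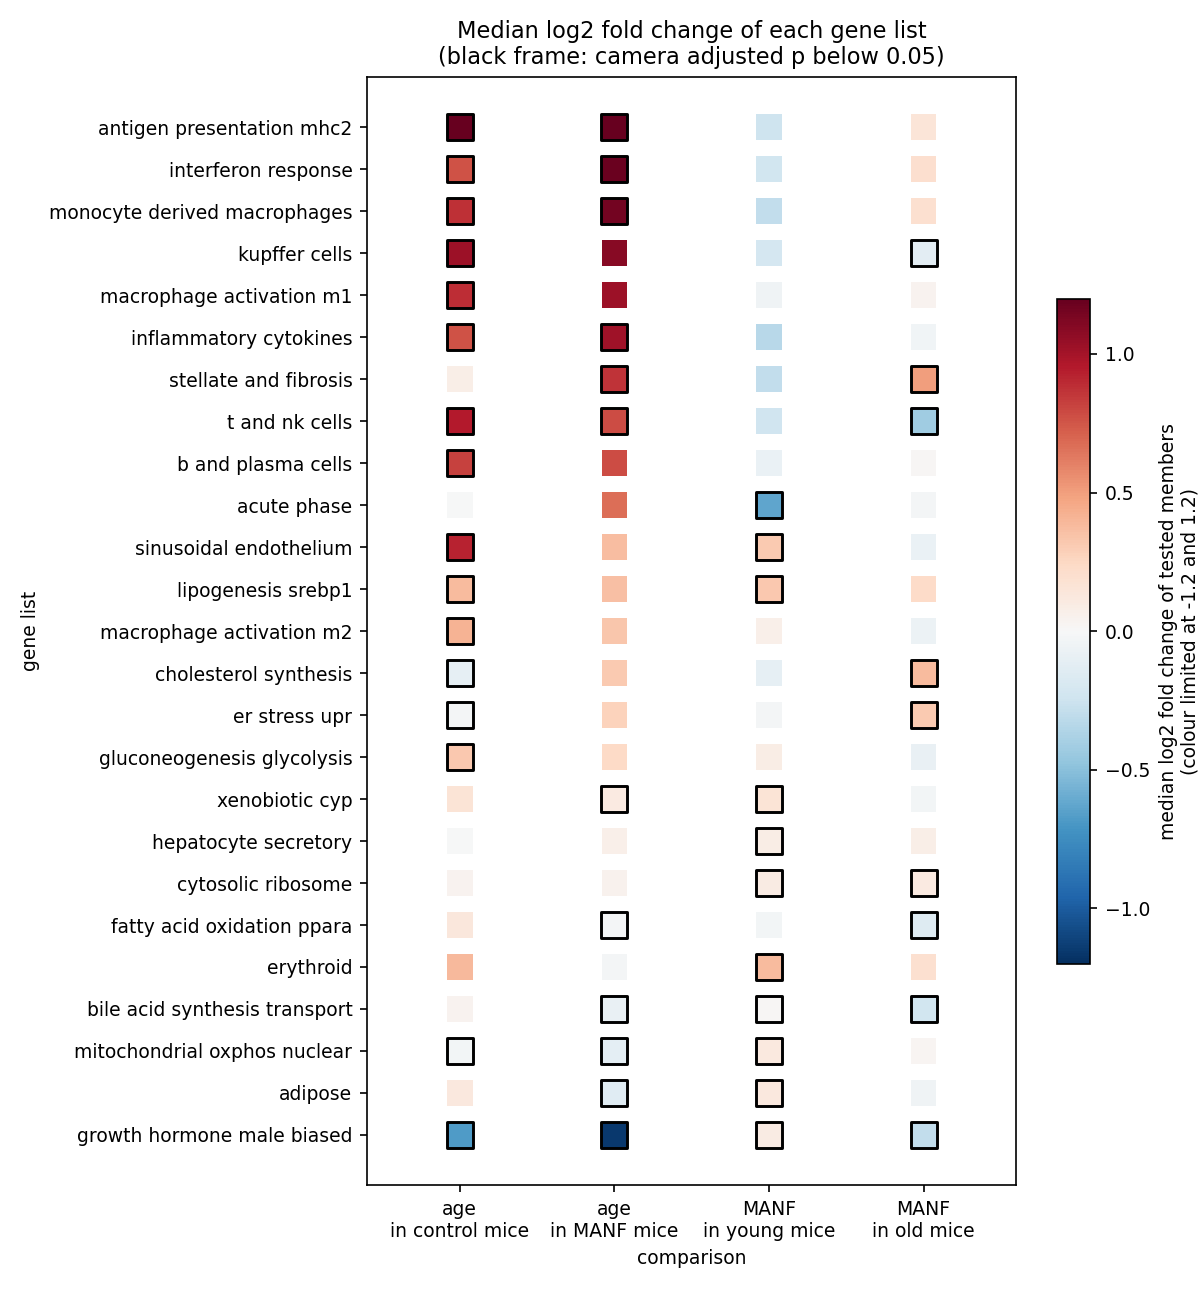
Colour shows the median log2 change, in 4 comparisons, of each gene list that was called in any of them, with the scale limited at -1.2 and 1.2. A black frame marks a camera adjusted p under 0.05 at the preset correlation of 0.01. With an estimated correlation the male-biased list in the age comparison of MANF mice kept its call (adjusted p = 0.00308) and the other framed lists lost theirs.

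Averaged over both ages, the genes that changed with MANF included the clock genes Nr1d1 and Dbp and the deiodinase gene Dio1. Nr1d1 rose by log2 1.399 (adjusted p = 3.67e-05), and Dbp (chromosome 7, 45705088 to 45710203, plus strand) by log2 0.83 (adjusted p = 0.0111). Dio1 fell by log2 -0.94 (adjusted p = 0.000929), from 74.3 ± 3.56 to 53.4 ± 9.09 RPKM in young mice and from 35.5 ± 5.19 to 13.4 ± 2.91 RPKM in old mice. The arrestin family gene Arrdc3 rose by log2 1.21, Cyp2c55 by 1.05, the predicted gene Gm15408 by 0.84, Agxt, the alanine-glyoxylate aminotransferase, by 0.82 and Cbs, the cystathionine beta-synthase, by 0.75. Trib3, Atf5, a transcription factor of the stress response, and the protease gene Prss8 rose by log2 0.93, 0.78 and 0.77. Tnnc1 and the acute phase gene Saa4 fell by 0.84 and 0.55 on the log2 scale. Ugt2b37 had a mean log2 change of -0.97, from -1.96 in young and 0.02 in old mice, where the controls held only 0.191 to 0.57 RPKM. Cyp21a1, Ugt2b38, the microRNA gene Mir5100, Tsku, Alas1, the first enzyme of heme synthesis, Sftpa1 and Nampt, an enzyme of NAD synthesis, fell by 1.10, 1.04, 0.97, 0.96, 0.87, 0.81 and 0.74. Nr1d1, Dbp, Dio1, Arrdc3, Cyp2c55, Gm15408, Agxt, Cbs, Ugt2b37, Tnnc1 and Saa4 kept their calls in each of the 16 runs that left out 1 library. The other 10 genes lost theirs in 4 to 13 of these runs, each of the 16 libraries ended at least 1 of these calls, and the highest adjusted p was 0.11. Of the 11 genes that kept their calls in all 16 runs, 10 also kept them in every other setting.

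**Figure D4:**
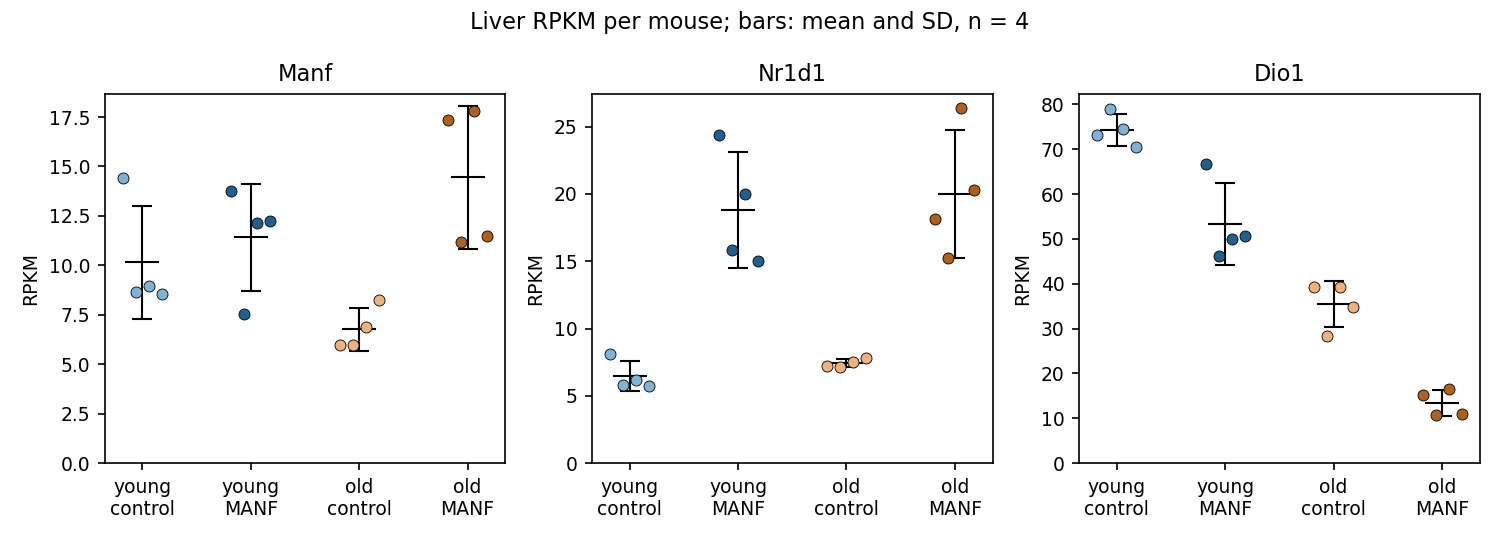
Points are the RPKM of Manf, Nr1d1 and Dio1 in each mouse of the 4 groups, and bars with whiskers are means ± SD (n = 4). In both ages all 4 MANF mice lie above all 4 controls for Nr1d1.

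The list of circadian clock genes showed changes in both directions. Over both ages 2 of 17 rose (Nr1d1 and Dbp), and 3 rose and 5 fell when adjusted over the list alone (fry p for change in either direction = 2.8e-08). Camera, which looks for a common direction, had an adjusted p of 0.868. Members that did not pass over all genes had log2 differences of -0.48 for Usp2, -0.48 for Per2, -0.37 for Cry1, -0.27 for Hlf, -0.14 for Clock, -0.11 for Nfil3 and 0.35 for Bhlhe41, with adjusted p of 0.144 to 0.689. Acute phase genes lay lower with MANF (median -0.40, 1 lower over all genes, 6 over the list alone, 2 of 20 above 0, camera adjusted p = 0.000408). ER stress genes lay higher (median 0.18, 1 higher over all genes, 3 over the list alone, 15 of 25 above 0, camera adjusted p = 0.000425), with Sdf2l1 and Calr at log2 0.56 and 0.37 (adjusted p = 0.105 and 0.0838) and Manf at 0.59 (0.0689). Sdf2l1 passed without old control replicate 4 (0.014), Calr without old control replicate 4 (0.03) or young MANF replicate 2 (0.042), and Manf without young control replicate 1 (0.036), young MANF replicate 2 (0.026) or old control replicate 4 (0.049) and under median scaling (0.047). Ribosome (27 of 27 above 0, camera adjusted p = 5.2e-05), lipid synthesis (16 of 19, 0.000204) and oxidative phosphorylation genes (22 of 25, 0.000408) lay slightly higher, with medians of 0.11, 0.22 and 0.08 and 0 members called by limma. Each of these 5 lists had an adjusted p of 0.976 with an estimated correlation.

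The 5 other lists called over both ages depended on single libraries, and each had an adjusted p of 0.976 with an estimated correlation. Hepatocyte secretory proteins (camera adjusted p = 0.0123) were not called without young MANF replicate 3 or old MANF replicate 3 (up to 0.0964). Cholesterol synthesis (0.024) was lost without young control replicate 1 or 3, young MANF replicate 1 or 4 or old control replicate 2 or 3 (up to 0.202). T and NK cell markers (0.0364), sinusoidal endothelium (0.0364) and stellate cell genes (0.0364) lost their calls in 8, 8 and 10 of the 16 runs, with adjusted p up to 0.181, 0.458 and 0.181, and each of the 16 libraries ended at least 1 of these 3 calls. In limma 138 genes were called over both ages, 63 higher and 75 lower with MANF. The larger side changed with the setting, with 85 higher and 64 lower after quantile normalization, 46 and 93 in voom, and 97 and 77 without old control replicate 4. The count was 87, 88 or 70 without young control replicate 1, 2 or 3, 59 without young MANF replicate 1, 72, 70 or 76 without old control replicate 1, 2 or 3, and 82 without old MANF replicate 4. Without old control replicate 4, interferon response (0.00136), monocyte-derived macrophages (0.0205) and MHC class II (0.00326) were called as higher with MANF, and fatty acid oxidation (0.000149) and the male-biased list (0.0181) as lower.

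The interaction asked whether MANF acted differently in old and young livers. Limma called 0 genes (smallest adjusted p 0.16, 894 genes at an unadjusted p under 0.05), and voom also called 0. The median log2 of all genes was 0.123 in this contrast and -0.005 after median scaling, a shift of 0.128. The genes with the smallest p were Ugt2b37 (log2 1.98, adjusted p = 0.16), Bmp5 (1.01, 0.197), the mitochondrial carbonic anhydrase gene Car5a (-0.66, 0.197), Mageh1 (1.05, 0.282) and Mtmr11 (1.76, 0.282). Bmp5 was read at 2.27 ± 0.270 and 1.395 ± 0.349 RPKM in young control and MANF livers, and at 1.64 ± 0.103 and 2.45 ± 0.392 RPKM in old ones. Without young MANF replicate 4, 2 genes were called, of which Bmp5 had an adjusted p of 0.043.

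At the level of lists, 17 differed between the ages in camera and 0 with an estimated correlation. Without old control replicate 4 there were 23, and among the 8 gained were interferon response (adjusted p = 2.07e-09, 0.0946 with all libraries), monocyte-derived macrophages (3.62e-05 and 0.349), MHC class II (0.000767 and 0.514) and cytokines (0.0013 and 0.929), each higher with MANF in old mice. Interferon response was also called under median scaling (0.00441). Among the 17 were stellate cell genes, which were relatively higher with MANF in old mice (median 0.83, 20 of 20 above 0, 6 higher over the list alone, camera adjusted p = 3.14e-06, 0.415 with an estimated correlation), and the male-biased list, which was lower (median -0.51, 3 of 21 above 0, 0 over the list alone, camera adjusted p = 4.76e-09, 0.118 with an estimated correlation). Lrat and Dcn had interaction log2 values of 1.33 and 0.84 and Cyp2d9 of -0.93 (adjusted p = 0.461, 0.532 and 0.594). Sinusoidal endothelium (median -0.41, camera adjusted p = 8.98e-09, 0.3 with an estimated correlation) and bile acid genes (median -0.39, camera adjusted p = 3.53e-08, 0.0608 with an estimated correlation) lay lower, with Oit3 at -0.73, Bmp2 at -0.81 and Cyp8b1 at -1.52 (each adjusted p = 0.594). ER stress genes lay higher (median 0.35, 23 of 25 above 0, camera adjusted p = 0.000567, 0.415 with an estimated correlation), as did acute phase genes (median 0.71, camera adjusted p = 0.0115, 0.707 with an estimated correlation) and genes of senescence and p53 (median 0.62, 12 of 12 above 0, camera adjusted p = 0.0121, 0.427 with an estimated correlation). Hspa5 had an interaction log2 of 0.81 and Saa2 of 3.05 (each adjusted p = 0.594). Saa2 was read at 220.0 RPKM in old control replicate 4 and at 10.5 to 15.7 RPKM in the other old controls. Acute phase lost its call without young control replicate 4, young MANF replicate 2, old control replicate 3 or old MANF replicate 3 (adjusted p up to 0.0878).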

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

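The tests for unspliced RNA and fat and the runs of the clock score without 1 library were chosen after the results were seen. For the other explanations the predictions were set down before their tests were run. Those for Nr1d1 and Dbp and for the libraries that stood apart address patterns found in these data. They were therefore not planned before the data were examined. Dixon's test was run within groups of 4 libraries on the RPKM of the named genes and on measures of depth, 366 sets of values in all. It set 1 library apart in 26, or 7.1%. The test allows 5% by chance for independent, normally distributed values. These sets share libraries and most genes were selected by their changes, so 5% is no reference for this share. Old control replicate 4 accounted for 5 of the 26 and young MANF replicate 3 for 2.

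In old control replicate 4 the gap to the other 3 old controls was large for Saa2 (220.0 RPKM, others 10.5 to 15.7), C1qa (142.0, others 22.8 to 29.9), Adgre1 (25.2, others 2.94 to 4.39), Rtp4 (19.6, others 6.63 to 8.49) and Sdf2l1 (11.9, others 5.5 to 6.44). In young MANF replicate 3, 7885 genes reached 1 RPKM (others 8376 to 8461), and Klrd1 was lowest at 0.121 RPKM (others 0.179 to 0.188).

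Single genes set apart other libraries. Old control replicate 1 was highest for Oit3 (7.5 RPKM, others 5.81 to 5.93) and Kdr (4.18, others 3.03 to 3.22), and old control replicate 2 for Moxd1 (0.075, others 0.0141 to 0.0147). Young control replicate 1 was highest for Manf (14.4 RPKM, others 8.57 to 8.95), Hspa5 (124.0, others 73.9 to 80.8) and Clock (2.19, others 1.69 to 1.77). Cd8a was highest in young control replicate 2 (0.419, others 0.082 to 0.0853). Young control replicate 3 was highest for Rgs16 (27.5, others 2.54 to 6.48), Nampt (31.2, others 21.4 to 22.9) and Trib3 (1.77, others 1.1 to 1.22). Cyp1a2 was lowest in young MANF replicate 2 (97.7, others 175 to 187), and Mtmr11 highest in young MANF replicate 4 (0.637, others 0.491 to 0.506). Old MANF replicate 1 was highest for Arrdc3 (34.8, others 17.4 to 19.9) and old MANF replicate 2 for Acly (91.7, others 59.6 to 61.8). Old MANF replicate 3 was highest for Mup11 (72.8, others 3.14 to 12.6), Lcn2 (37.2, others 6.53 to 11.3) and Ugt2b37 (0.807, others 0.284 to 0.344). In old MANF replicate 4 Cxcl1 was highest (5.83, others 3.91 to 4.11) and Tsku lowest (3.46, others 10.1 to 10.7).

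The effect of MANF differed between old and young mice, by a camera test of the interaction, in 17 lists. Lower in old mice were the male-biased list (adjusted p = 4.76e-09), sinusoidal endothelium (8.98e-09), bile acid genes (3.53e-08), oxidative phosphorylation (3.14e-06), xenobiotic metabolism (0.000218), fatty acid oxidation (0.000218), gluconeogenesis and glycolysis (0.000678), lipid synthesis (0.00201), T and NK cells (0.0209), erythroid cells (0.0418), Kupffer cells (0.0446) and adipose markers (0.0454). Higher were stellate cells (3.14e-06), ER stress (0.000567), acute phase (0.0115), senescence and p53 (0.0121) and cholangiocytes (0.032). With an estimated correlation the smallest adjusted p was 0.0608, for bile acid genes and xenobiotic metabolism. Of the 16 runs that left out 1 library, 9 ended the call of Kupffer cells (adjusted p up to 0.784), 9 that of adipose markers (0.127), 7 that of erythroid cells (0.532), 7 that of cholangiocytes (0.0649), 5 that of T and NK cells (0.349), 4 that of acute phase (0.0878) and 2 that of lipid synthesis (0.139). Without old control replicate 4, 23 lists were called, 15 of them among the 17. Median scaling ended the calls of Kupffer cells (0.455), erythroid cells (0.227), adipose markers (0.183) and T and NK cells (0.143).

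Nr1d1 and Dbp, both under circadian control, were higher with MANF in both ages, and if the MANF livers were at another clock phase, genes of the opposite phase should lie lower in them. The mean log2 of Arntl, Npas2, Clock, Cry1 and Nfil3 differed by -0.119 (SE 0.054, exact permutation p = 0.0392 over 4900 permutations) and by -0.121 in young and -0.116 in old mice, but without young MANF replicate 3 the young value was -0.058 (-0.087 over both ages, p = 0.0808), and p was 0.05 or more in 9 of the 16 runs without 1 library (up to 0.0833). Another time of collection or a shift of the clock may still account for these genes, though the evidence hangs on single libraries. Of the 5, Cry1 (-0.33 in young and -0.415 in old mice), Clock in young mice (-0.291) and Nfil3 in old mice (-0.253) carried the score, while Clock in old mice differed by 0.009 and Nfil3 in young mice by 0.033, Arntl and Npas2 were read at 0.216 RPKM or less, and with no hour of collection in the labels a difference in collection and an effect of MANF on the clock could not be separated. Scaling of the libraries was excluded as the cause, since Nr1d1 kept a log2 change of 1.412 after median scaling.

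Old control replicate 4 lay above the other old controls in immune and acute phase genes, and its Alb was 20090 RPKM. A lower share of hepatocytes would raise the markers of all other cells alike. T and NK cell markers rose by a median log2 of 0.973 and endothelium markers by 0.201, a difference of 0.772 (SE 0.271 across genes). That SE treats the genes of 1 library as independent and does not measure the spread between mice. The difference therefore cannot exclude a lower share of hepatocytes. Pancreas and muscle were excluded, since the summed RPKM of their genes were 0.337 and 0.82 of the highest other library. Fat in the sample was excluded too, since the sum of Adipoq, Plin1, Lep and Retn, which are abundant in fat, was 0 RPKM (at most 0.108 in the other libraries). Lymphoid or other tissue was not tested, and no biological explanation was, because the design gives none for a single mouse.

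For young MANF replicate 3, GC content and gene length explained 38% of the variance of its log2 deviations, against at most 23.5% in the other 15 libraries (Spearman 0.576 with GC content and -0.458 with length, 10545 genes). A bias by GC content and length might therefore account for part of its distance. Small RNA genes lay at -0.31 relative to the other genes, where more unspliced RNA needs a value above 0. This difference was not adjusted for GC content or length, which the deviations of this library follow, so it cannot exclude that explanation. No biological explanation was tested here either.

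Each comparison was repeated with its libraries regrouped. Of 35 splits of the 8 libraries, the real one was the only one to reach its count for age in control mice (133 calls, highest other 36), age in MANF mice (702, highest other 1) and MANF in young mice (2, highest other 1), that is 1 split of 35 each. For MANF in old mice, 3 of 35 splits called at least as many genes as the real one (11 calls, highest other 38), and whether chance could give that number is left open. The split with 38 set old control replicates 1, 2 and 3 and old MANF replicate 1 against the rest, which moves old control replicate 4 and keeps 3 controls and 3 MANF mice on their real sides. The real grouping called 146 genes without old control replicate 4. The other splits were not repeated without that library, so this count does not bear on whether chance could give the calls. Over both ages 1 of 100 splits within age reached the real count (138, highest other 5). For the interaction 100 of 100 did, since the real count was 0 (highest other 2).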

How the results depend on the processing

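Voom on the recovered reads, the fit without both old control replicate 4 and young MANF replicate 3, and the lists without each library were chosen after the results had been seen. Across the alternatives the named genes kept direction and side of the threshold in 2820 fits, ended past the threshold in 31 and short of it in 554, and turned in 0. The Manf comparisons of young and old mice were unchanged with pseudocounts of 0.1 and 1. A library outside the compared groups changes the calls of a contrast only through the spread estimated over all libraries. Where no cause is given below, the cause was not tested.

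For age in control mice, leaving out 1 library gave 37 to 132 calls (main count 133), and leaving out both libraries 229. The lists called numbered 16 with camera, 0 with an estimated correlation and 3 with fry. For age in MANF mice (702 calls) a minimum of 2 RPKM gave 388, median scaling 319, quantile normalization 247, voom 260, only the compared groups 1072, leaving out 1 library 216 to 1125 and leaving out both 1406. Scaling removes the shift of 0.176 in the median of all genes. Of 12 lists 1 was left with an estimated correlation. Fry called 9 lists (8 higher and 1 lower), 6 of them among the 12, and median scaling 18, 9 of them among the 12.

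For MANF in young mice (2 calls) the compared groups alone gave 5. Of 11 lists 0 were left with an estimated correlation, 0 with fry and 7 with median scaling. For MANF in old mice (11 calls) a pseudocount of 0.1 gave 3, no filter 3, a minimum of 2 RPKM 3, quantile normalization 17, the compared groups alone 6, leaving out 1 library 2 to 146 and leaving out both 362. Of 9 lists 0 were left with an estimated correlation and 0 with fry. Without 1 library 8 to 14 lists were called, 7 to 9 of them among the 9. Over both ages (138 calls) no filter gave 86, leaving out 1 library 59 to 174 and leaving out both 209. Of 10 lists 0 were left with an estimated correlation and 0 with fry. Without 1 library 6 to 13 lists were called, 6 to 9 of them among the 10. The interaction (0 calls) gave 0 to 2 without 1 library and 1 without both. Of 17 lists 0 were left with an estimated correlation and 0 with fry.

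The correlation of the age change in control mice with the effect of MANF in old mice (r = -0.191) was -0.107 with a minimum of 2 RPKM, and -0.293 to -0.128 without 1 library. With split old controls it averaged 0.049, with 2 old controls left in each contrast. The splits that stayed below 0, 3 of 6, were those with old control replicate 4 in the MANF contrast. Why this library turned the sign was not tested.

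The replicate numbers are shared between groups, but the labels do not pair the animals. Deviations of libraries with the same number had correlations of -0.319 to 0.21 (median 0.0095, others -0.014), with 5 of 24 above 0.1, and 2 of 16 libraries correlated best with their own number. With a replicate block the calls were 85 for age in control mice, 459 for age in MANF mice, 6 for MANF in old mice and 95 over both ages.

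At the depth reached, 1 RPKM for a gene of 2 kb corresponded to 36.6 to 52.2 reads, and genes that reached 0.5 RPKM in fewer than 4 libraries, such as Cdnf (3 to 20 reads), were not tested.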

Other observations

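Cd36 in MANF mice and Hspa8 and Rrm2 in control mice, chosen after their values were seen, also differed with age. Cd36, a member of the list for lipid droplets and steatosis, rose in both age comparisons, from 6.00 ± 2.38 to 17.2 ± 2.61 RPKM in control mice (adjusted p = 0.00195) and from 6.42 ± 0.920 to 18.3 ± 0.659 RPKM in MANF mice (adjusted p = 0.0016), while the list was not called in control mice (12 of 16 genes above 0, camera adjusted p = 0.089, 0.638 with an estimated correlation, and 0.01 without old control replicate 4). In control mice the chaperone gene Hspa8 rose from 99.6 ± 25.0 to 183 ± 31.2 RPKM (adjusted p = 0.0262), a call lost without young control replicate 2 or 4 or old control replicate 1 or 3 (up to 0.084). Rrm2, a subunit of ribonucleotide reductase, rose from 2.04 ± 0.638 to 4.62 ± 0.112 RPKM (adjusted p = 0.0309), a call lost without any 1 library except young control replicate 3 (up to 0.1). The lists that hold them, cytosolic heat shock and cell cycle, were not called in control mice (1 of 12 and 1 of 9 genes higher, camera adjusted p = 0.562 and 0.297, 0.943 and 0.781 with an estimated correlation). Female-biased genes had 7 of 8 above 0 and 5 higher when adjusted over the list alone, with 0 higher in limma over all genes (camera adjusted p = 0.056, 0.516 with an estimated correlation). That list was called under median scaling (0.03) and without old control replicate 4 (0.00323).

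Among 12 genes of senescence and p53, 2 rose with age in MANF mice and 12 were above 0 (median 0.69, camera adjusted p = 0.0609, 0.661 with an estimated correlation). Cdkn1a, the gene of the cell cycle inhibitor p21, rose from 0.326 ± 0.110 to 2.45 ± 1.36 RPKM (log2 1.71, adjusted p = 0.0367), and Phlda3 from 0.208 ± 0.068 to 0.789 ± 0.266 RPKM (log2 0.85, adjusted p = 0.0315). Both calls were lost without young MANF replicate 1, 2 or 3 or old MANF replicate 2, 3 or 4 (up to 0.091 and 0.075) and under median scaling (0.066 each), under which the list itself was called (0.00421). In control mice the log2 changes of Cdkn1a and Phlda3 were 0.74 and 0.08 (adjusted p = 0.483 and 0.91), and the differences between the age changes were not called (interaction adjusted p = 0.635 and 0.594).

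A hypothesis was that MANF moves the age profile of old liver back toward that of young liver. It predicts a negative correlation between the age change and the effect of MANF when the groups compared share no libraries. With the old controls split into 2 and 2, the mean r over 6 splits was 0.049 (-0.202 to 0.273), with 3 of 6 below 0, so that the hypothesis could be neither held nor excluded with 4 mice per group. The splits with r above 0 were those that used old control replicate 4 for the age change.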
